A study of Homo sapiens with 16 samples.

How the data were processed

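Small RNA was sequenced from primary cultures of human skeletal muscle cells. Per the labels' protocols, cells at partial confluence were transfected with siRNA against the vitamin D receptor (VDR) or with scrambled siRNA, and the control arm carries the name baseline. The hormone 1,25-dihydroxyvitamin D3 (1,25D), the ligand of VDR, was given at 10 nM in ethanol, or ethanol alone was given, 48 and 24 hours before RNA was isolated. The 4 combinations of arm and agent hold 4 libraries each. The labels number the libraries of a group 1 to 4 and do not say whether the numbers stand for donors or cultures. Per the labels' protocols, each library was made from 500 ng of total RNA with a ligation-based small RNA kit, 15 cycles of PCR and one of 8 index primers. Equimolar vehicle and hormone libraries were then pooled, size-selected and sequenced on single-end Illumina flow cells.

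The deposited table holds counts, as whole numbers, for 2042 mature miRNA names in 16 columns, one per library. Per the submitters' processing notes, CASAVA and Bowtie were used with genome build hg19. The version and role of each tool, adapter trimming, the miRNA annotation release and the treatment of reads that match several loci are not given in the sources used here. The table gives miRNA names without coordinates, so no positions are printed. VDR is not a miRNA and is not in the table, so the depth of the knockdown was not analysed here.

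Counts were analysed with edgeR 4.0.16 in R 4.3.3. A miRNA was tested when it passed the default expression filter of edgeR for the 4 groups, which kept 214 of the 796 miRNAs with a count. Library sizes were scaled by the trimmed mean of M-values (TMM). One quasi-likelihood model with a mean for each of the 4 groups was fitted to all 16 libraries, and each comparison was a contrast of that model. P-values were adjusted by the method of Benjamini and Hochberg within a comparison, at a threshold of 0.05. All tests were two-sided. Fold changes are given on the log2 scale with a standard error (SE), and levels as CPM (counts relative to the TMM-scaled total of the tested miRNAs in the library) with the SD over 4 libraries. The estimated coefficient of biological variation was 0.317. The p-values measure the spread between libraries, which may be technical or between cultures. A single count equalled 4.17 to 22.0 CPM, and a count of 0 allowed up to 12.5 to 66.0 CPM (3 counts). Such limits cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules.

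The model and the comparisons, the lists of miRNAs, the rule for naming miRNAs and the alternatives, apart from those named as added, were fixed before the data were examined. The rule named up to 10 rising and 10 falling miRNAs by p-value among those past the threshold, or the 5 with the smallest p where none passed. It also named each tested miRNA of the myomiR list and of the list described to target FOXO1, and each list member past the threshold over all miRNAs or over its list alone. The lists with biological themes were myomiRs, other miRNAs described in myoblast proliferation or differentiation (the myoblast list), miRNAs described to target VDR or FOXO1, miRNAs described as responsive to 1,25D in other cells, the let-7 family, the miR-17/92 cluster and its paralogs, miR-34, inflammation, fibrosis, hypoxia and the imprinted 14q32 cluster. Marker lists covered endothelial, blood, smooth muscle and fibroblast, epithelial, neural and hepatocyte miRNAs and the placental C19MC cluster. Lists with at least 3 tested members were compared with the other miRNAs by camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation, on log2 CPM with a prior count of 2. The fry test of limma asked whether the members of a list moved one way on balance. It makes no comparison with other miRNAs.

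The alternatives were size factors of DESeq2 in the edgeR model, library totals without TMM factors, no filter, a filter of at least 10 CPM in 4 libraries, a block for the number in the titles, only the libraries compared, the Wald test of DESeq2 1.42.0, limma-voom, and each library left out in turn. Added after the data were seen were the averages of both 1,25D contrasts and of both knockdown contrasts, the removal of a pair of baseline libraries, thinning of every library to 44440 counts, and an offset per library for the GC content of the hairpin. Hairpin sequences came from the GENCODE v29 transcripts, where all 214 tested miRNAs had a match by name, and served for GC content alone.

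The edgeR steps were tested on simulated counts for the 796 detected miRNAs, with 200 changed, in 20 simulations for each of 2 comparisons. For 1,25D in baseline cells, 13.2% of tested miRNAs changed 1.5-fold were called, 52.7% of those changed 2-fold, 88.9% at 3-fold and 95.2% at 4-fold, with 0.766% of unchanged miRNAs called. For knockdown in ethanol the percentages called were 16.6 at 1.5-fold, 49.5 at 2-fold, 83.8 at 3-fold, 93.7 at 4-fold and 0.922 of unchanged miRNAs. These percentages hold for 200 of 796 miRNAs changed at once. Where fewer miRNAs change, the adjustment is stricter and a smaller percentage is called.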

Results

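Mature miRNAs were counted in 16 small RNA libraries from primary human skeletal muscle cells. The 4 groups of 4 libraries were baseline or VDR knockdown cells, each given ethanol or 1,25D. Total counts averaged 160880 ± 40998 (SD, n = 4) in baseline cells with ethanol and 175374 ± 41239 with 1,25D. In knockdown cells they averaged 67526 ± 22414 with ethanol and 65902 ± 15078 with 1,25D. Every baseline library (126480 to 232874 counts) was deeper than every knockdown library (44440 to 86938), and the ratio of the median totals was 2.40 (exact permutation p = 0.000155, two-sided, 8 libraries against 8).

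**Figure D1:**
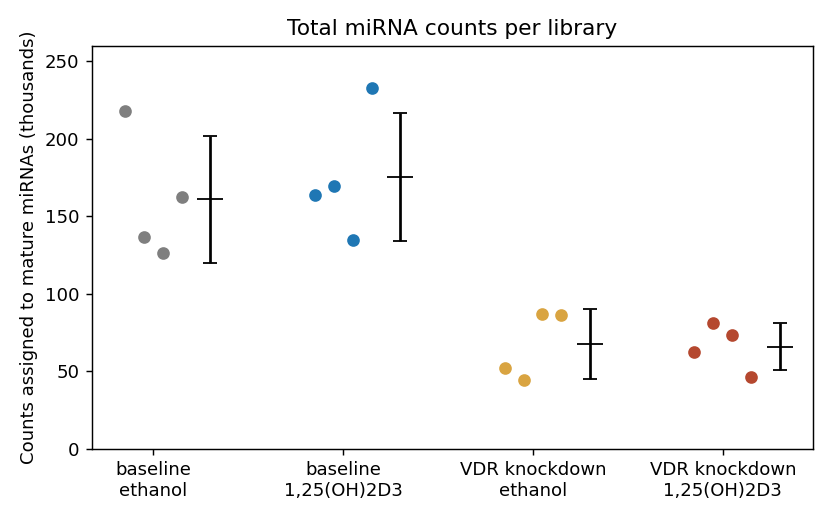
Total miRNA counts per library, in units of 1000 counts, for the 4 groups; points are libraries and bars show the mean and SD (n = 4). The 8 knockdown libraries lie below the 8 baseline libraries.

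The cells' miRNA pool was led by miR-423-3p with 13.2% ± 1.96 of counts (SD, n = 16), miR-92a-3p with 10.3% ± 2.20, miR-370 with 9.90% ± 3.11 and let-7b-5p with 6.02% ± 1.26. The myomiRs, the muscle-enriched miRNAs, took 0.648% ± 0.321 of counts in baseline cells with ethanol (n = 4), mostly as miR-206, and the 14q32 imprinted cluster took 13.4% ± 1.31. Markers of other cell types were near or at 0, with 10 counts over all 16 libraries for the endothelial list, 4 for blood, 33 for epithelial and 18 for the hepatocyte marker. The neural and C19MC lists had 0 counts, which allows a share of up to 3 counts in each library. No member of these 6 lists was tested. The smooth muscle and fibroblast markers had 2 tested members, miR-143-3p and miR-145-5p. In baseline ethanol library 1, miR-143-3p had 1373 counts, whereas each other baseline library had between 40 and 106. That library and baseline 1,25D library 4 lay farthest from the knockdown libraries on the first principal component (30.4% of the variance), at -11.0 and -5.97, against -3.81 to 0.53 for the other baseline libraries. Within 2 pairs of names, miR-1260a with miR-1260b and miR-1268a with miR-1268b, counts differed in every library by less than 0.15 of their sum, so the members of a pair may share reads and are not independent.

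The comparison of 1,25D with ethanol in baseline cells asks which miRNAs respond to the hormone. miR-133a, which supports the proliferation of myoblasts, had 346 ± 143 CPM with ethanol and 169.8 ± 42.7 CPM with 1,25D (log2 fold change -1.03, SE 0.46). miR-206, which promotes differentiation, differed by 0.09 (SE 0.42), and miR-486-5p by 0.04 (SE 0.34). miR-27a-3p, described to target FOXO1, differed by -0.32 (SE 0.39). The miRNAs with the smallest p were miR-143-3p (-2.0, SE 0.68), miR-129-5p (0.76, SE 0.28), miR-532-3p (-0.97, SE 0.39), miR-181b-5p (-0.48, SE 0.20) and miR-125b-1-3p (0.44, SE 0.19). The value of miR-143-3p rested on baseline ethanol library 1 and was 0.29 without it. It was also the 1 miRNA past the threshold when adjusted over the list alone, in the smooth muscle and fibroblast list, and no other list had such a member.

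None of the 214 miRNAs passed the threshold in this comparison by edgeR (0 calls, 9 with an unadjusted p under 0.05, smallest adjusted p = 0.955). DESeq2 called 0 (7 unadjusted) and limma-voom 0 (8 unadjusted). For 114 miRNAs the whole 95% interval lay inside a 2-fold change. All 8 tested members of the fibrosis list had lower estimates with 1,25D (median log2 fold change -0.48; camera adjusted p = 0.0460), but the call was lost with an estimated correlation (adjusted p = 0.507 with an estimated correlation), and fry gave an adjusted p of 0.743. The list includes miR-143-3p, and its adjusted p was 0.898 without the pair of baseline libraries apart. Its members miR-199a-3p and miR-199b-3p, with 1134 and 567 counts over all libraries, may share reads, so the 8 are not independent. All 11 tested miRNAs described as responsive to 1,25D in other cells also had lower estimates (median -0.29), with 0 past the threshold and no camera call (adjusted p = 0.0849; 0.524 without the pair of libraries apart; adjusted p = 0.507 with an estimated correlation).

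In VDR knockdown cells the same comparison asks which responses remain when the receptor is depleted. miR-129-5p had 297 ± 82.3 CPM with ethanol and 542 ± 58.5 CPM with 1,25D (n = 4), a log2 fold change of 0.86 (SE 0.30). The others with the smallest p were miR-1292-5p (-1.12, SE 0.31), miR-296-5p (-1.82, SE 0.59), miR-3656 (-1.46, SE 0.50) and miR-152 (2.02, SE 0.73). Both of the last rested on few counts, with 0 to 4 per ethanol library for miR-152, whose value was 3.31 without knockdown ethanol library 1, and miR-3656 was -0.93 without knockdown ethanol library 3. miR-133a differed by -0.21 (SE 0.64), miR-206 by 0.47 (SE 0.43), miR-486-5p by 0.15 (SE 0.35) and miR-27a-3p by 0.19 (SE 0.42). edgeR called 0 of 214 miRNAs (9 with an unadjusted p under 0.05, smallest adjusted p = 0.399), DESeq2 0 (10 unadjusted) and limma-voom 0 (9 unadjusted). No list passed by camera (smallest adjusted p = 0.271), and 94 miRNAs had a 95% interval inside a 2-fold change.

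The difference between the effects of 1,25D in knockdown and in baseline cells asks whether the response depends on VDR. It was -1.25 (SE 0.41) for miR-1292-5p, -1.33 (SE 0.49) for miR-1268a, -1.91 (SE 0.73) for miR-3656, 2.25 (SE 0.87; 3.40 without knockdown ethanol library 1) for miR-152 and -1.23 (SE 0.48) for miR-1268b, on the log2 scale. For the muscle miRNAs it was 0.82 (SE 0.80) for miR-133a, 0.38 (SE 0.60) for miR-206 and 0.10 (SE 0.49) for miR-486-5p, and it was 0.52 (SE 0.57) for miR-27a-3p. No miRNA and no list passed by edgeR and camera (0 calls, 9 with an unadjusted p under 0.05, smallest adjusted p = 0.793 for miRNAs and 0.316 for lists), and DESeq2 (9 unadjusted) and limma-voom (8 unadjusted) also called 0. The median 95% interval reached 1.06 on either side, so a difference of less than about 2-fold was not detectable for most miRNAs. That interval is not adjusted over the 214 miRNAs, as the calls were, so larger differences could be missed too. Across the 214 miRNAs, which are not independent replicates, the effects of 1,25D in the arms had a Pearson r of 0.17 and a Spearman rho of 0.18, and 119 had the same sign.

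The comparison of VDR knockdown with baseline cells in ethanol asks what loss of the receptor changes without added hormone. The miR-221/222 pair, abundant in proliferating myoblasts and known to repress the cell-cycle inhibitor p27, fell. miR-222-3p went from 39936 ± 6692 to 22051 ± 6822 CPM (n = 4; log2 fold change -0.86, SE 0.24, adjusted p = 0.0246) and miR-221-3p from 11790 ± 4180 to 5546 ± 1416 CPM (-1.09, SE 0.27, adjusted p = 0.0126), and miR-221-5p fell as well (-1.74, SE 0.47). miR-133a fell from 346 ± 143 to 107 ± 40.0 CPM (-1.66, SE 0.54, adjusted p = 0.0422). Its fellow myomiRs miR-206 (-0.49, SE 0.43) and miR-486-5p (-0.19, SE 0.35) did not pass the test, and neither did miR-27a-3p (-0.00, SE 0.42). Falls were also called for miR-155-5p (-0.93, SE 0.31), an immune and inflammation miRNA, for miR-181b-5p (-0.68, SE 0.21), for miR-23b-3p (-1.48, SE 0.43) and for miR-145-5p (-1.86, SE 0.56), a smooth muscle miRNA with few counts here. miR-93-5p of the miR-17/92 paralogs (-1.38, SE 0.38), miR-543 (-1.13, SE 0.32) and miR-1185-1-3p (-1.08, SE 0.32) of the 14q32 cluster, and miR-339-5p (-1.13, SE 0.30) fell too. The 5 falling miRNAs outside the naming rule, chosen after their values were seen, were miR-483-3p, miR-4521, miR-1303, miR-484 and miR-15b-5p.

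The miRNAs that rose were mostly of low abundance in baseline cells. miR-4488 rose from 466 ± 175 to 1648 ± 889.2 CPM (n = 4; log2 fold change 1.85, SE 0.40, adjusted p = 0.00562) and miR-3656 from 33.9 to 198 CPM (2.63, SE 0.49, adjusted p = 0.00450). Increases were also called for miR-3960 (2.60, SE 0.54), miR-6087 (1.95, SE 0.47), miR-4516 (1.91, SE 0.40), miR-1268a (1.73, SE 0.35), miR-1268b (1.71, SE 0.35), miR-204-3p (1.05, SE 0.25), miR-193a-5p (0.95, SE 0.25) and miR-1260a (0.95, SE 0.26). miR-193a-5p and miR-1260a were abundant, with 10924 and 28211 CPM in baseline cells. The remaining 3, outside the rule and chosen after their values were seen, were miR-1260b, miR-125b-1-3p and miR-1246. Counts of the pairs miR-1260a/b and miR-1268a/b may come from the same reads. At 33.9 CPM in baseline cells miR-3656 rested on few counts, since 3 counts equal 13.0 to 24.0 CPM in those libraries. With the hormone present its change with knockdown was 0.73 (SE 0.54).

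**Figure D2:**
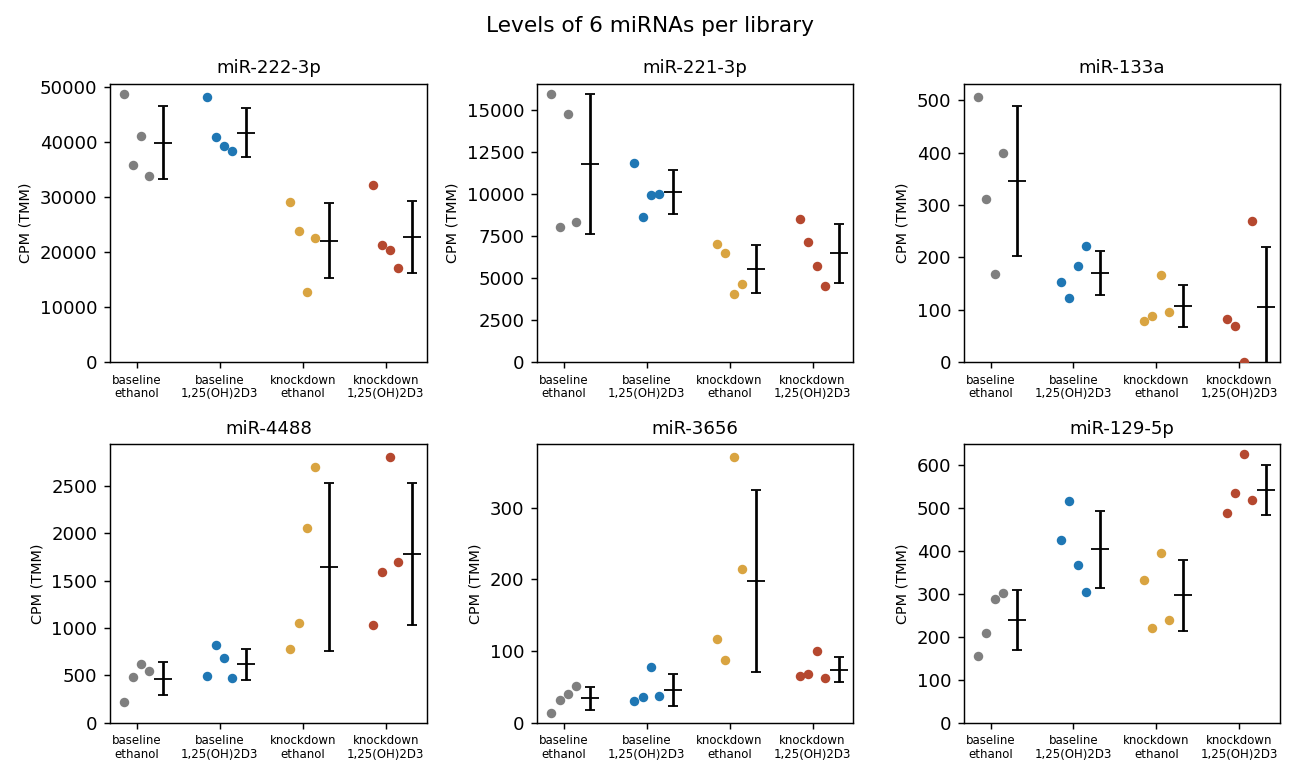
Levels per library in CPM (TMM-scaled) of miR-222-3p, miR-221-3p, miR-133a, miR-4488, miR-3656 and miR-129-5p in the 4 groups; points are libraries and bars show the mean and SD (n = 4), drawn down to 0 for miR-133a in knockdown cells with 1,25D, where the SD exceeds the mean. In ethanol the first 3 fell and miR-4488 and miR-3656 rose with knockdown, whereas no change of miR-129-5p passed the test.

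As a group, the myoblast list took 13.9% ± 2.37 of counts in baseline cells and 8.88% ± 1.48 in knockdown cells in ethanol (SD, n = 4). Of its 18 tested members 16 were lower, with a median log2 fold change of -0.61, and 5 fell past the threshold (miR-155-5p, miR-181b-5p, miR-221-3p, miR-222-3p and miR-23b-3p; the same 5 adjusted over the list alone). Camera gave an adjusted p of 0.00356, and the call was lost with an estimated correlation (adjusted p = 0.392 with an estimated correlation). Its fry adjusted p was 0.0123, and without the pair of baseline libraries apart the camera adjusted p was 0.0561. In the miR-17/92 list 1 of 4 tested members fell, and 2 adjusted over the list alone, the second being miR-25-3p (-1.43, SE 0.56; camera adjusted p of the list = 0.263, fry 0.0180). The single tested hypoxia miRNA, miR-210, had a value of -0.91 (SE 0.35; adjusted p over all miRNAs = 0.0992), and with 1 member the adjustment over the list alone leaves its p unadjusted, a level that 63 of the 214 miRNAs reached. In the 14q32 cluster 2 of 23 fell (camera adjusted p = 0.306; fry adjusted p = 0.00119). Of the list responsive to 1,25D 3 of 11 fell (miR-145-5p, miR-155-5p and miR-181b-5p; camera adjusted p = 0.263), of inflammation 1 of 6 (0.277), of fibrosis 1 of 8 (0.444), of myomiRs 1 of 3 (0.403) and of the smooth muscle and fibroblast markers 1 of 2, each with the same members adjusted over the list alone. The VDR-targeting list had 0 of 5 past the threshold with all 5 lower (camera adjusted p = 0.275, fry 0.0388) and let-7 had 0 of 8 (0.762). Of those 5, miR-27a-3p was near no change and ranged from -0.29 to 0.39 with single libraries left out. All but miR-125a-5p are also on the myoblast list, so the VDR-targeting list is not a separate result. miR-34a-5p, the tested miRNA of its list, differed by -0.76 (SE 0.44), and the 2 tested members of the FOXO1 list were not called.

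By edgeR 30 of 214 miRNAs passed, 13 up and 17 down, against 33 by DESeq2 (16 up, 17 down) and 27 by limma-voom (13 up, 14 down). With the size factors of DESeq2 in edgeR there were 14 up and 9 down, and miR-133a, miR-155-5p and miR-181b-5p no longer passed. The number of falls depended on single libraries more than the number of rises. It was 4 of 12 calls without baseline ethanol library 1, 7 of 18 without library 2 and 6 of 19 without library 4, and 2 of 15, 2 of 15 and 1 of 13 without knockdown ethanol libraries 2, 3 and 4. Leaving out baseline library 3 gave 8 falls of 21 calls and leaving out knockdown library 1 gave 11 of 27. miR-1268a, miR-1268b, miR-3960, miR-4516, miR-4488, miR-204-3p and miR-6087 stayed past the threshold with any of the 8 libraries left out. miR-3656 stayed past it without each of the 4 knockdown libraries and fell below the filter, so was not tested, without each of the 4 baseline libraries. miR-193a-5p and miR-1260a lost their calls without baseline ethanol library 1 (0.76 and 0.78) and without knockdown ethanol library 3 (0.83 and 0.82). Each falling miRNA named lost its call with 3 to 7 of them left out. The values then ranged from -0.94 to -0.55 for miR-222-3p, -1.15 to -0.75 for miR-543 and -1.03 to -0.61 for miR-155-5p. With only the 8 libraries compared there were 9 rises and 0 falls, and without the pair of baseline libraries apart 8 rises and 1 fall. With an offset for hairpin GC content there were 16 rises and 11 falls, and miR-222-3p, miR-543, miR-1185-1-3p, miR-181b-5p, miR-145-5p, miR-133a and miR-155-5p no longer passed. With all libraries thinned to 44440 counts the median over 20 draws was 14.5 calls (9 to 24; 161 miRNAs tested). The arms also differed in depth, and the labels do not say which libraries shared a pool, so the arm and a pool or sequencing batch cannot be told apart.

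The comparison of VDR knockdown with baseline cells in 1,25D asks the same with the hormone present. miR-222-3p averaged 41730 CPM in baseline and 22719 CPM in knockdown cells (log2 fold change -0.88, SE 0.24, n = 4). miR-4488 differed by 1.54 (SE 0.39), miR-4516 by 1.47 (SE 0.38), miR-3960 by 1.98 (SE 0.52) and miR-1185-1-3p by -1.24 (SE 0.33). The values were -0.84 (SE 0.57) for miR-133a (-1.75 without knockdown 1,25D library 4 and -0.37 without library 3), -0.11 (SE 0.43) for miR-206, -0.08 (SE 0.34) for miR-486-5p and 0.52 (SE 0.40) for miR-27a-3p. None passed by edgeR (0 calls, 34 with an unadjusted p under 0.05), but 10 had an adjusted p between 0.05 and 0.06, the smallest being 0.0506. DESeq2 called 9 (6 up, 3 down; 33 unadjusted) and limma-voom 0 (31 unadjusted). Leaving out knockdown 1,25D library 1 gave 7 calls in edgeR and leaving out library 3 gave 2. A block for the number in the titles gave 7 (3 up, 4 down). miR-222-3p, miR-93-5p (-1.18, SE 0.37) and miR-1185-1-3p passed when adjusted over the list alone. Of the 18 members of the myoblast list 15 were lower (median -0.41; camera adjusted p = 0.00524), and that call was lost too (adjusted p = 0.450 with an estimated correlation; fry adjusted p = 0.117). Its share of counts was 12.5% ± 1.37 in baseline and 9.17% ± 1.12 in knockdown cells. No other list passed by camera (smallest adjusted p = 0.295).

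The effects of knockdown with and without the hormone share no library. All 30 miRNAs called in ethanol had the same sign in 1,25D, as did 173 of all 214 tested, and 15 of the 30 had an unadjusted p under 0.05. The 13 that rose had a median log2 fold change of 1.71 in ethanol and 0.73 in 1,25D, and the 17 that fell had medians of -1.13 and -0.77. These miRNAs were chosen by their values in ethanol, so the smaller medians in 1,25D do not show a weaker effect with the hormone. A difference of pool, depth or GC content between the arms may enter both comparisons alike. Across all 214 miRNAs, which are not independent replicates, Pearson's r was 0.74 and Spearman's rho 0.72. All 4 knockdown libraries lay outside the range of the 4 baseline libraries for 36 miRNAs in ethanol and 23 in 1,25D, where chance gives 2.86% of miRNAs (6.11). This held under both agents for 11 miRNAs, among them miR-221-3p, miR-222-3p, miR-181b-5p, miR-339-5p, miR-4488, miR-4516 and miR-3960.

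**Figure D3:**
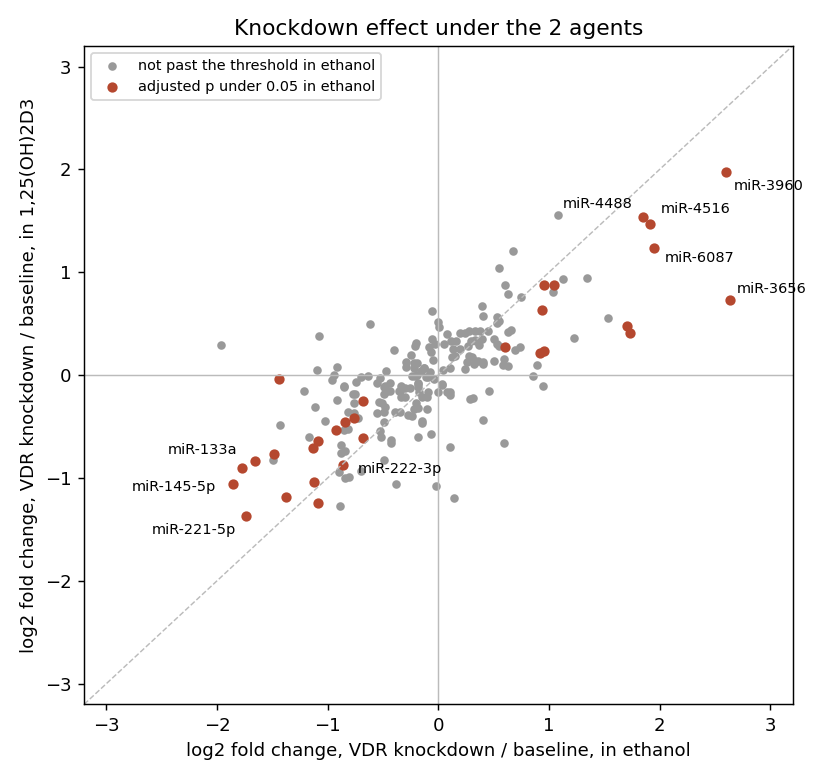
Log2 fold change of VDR knockdown against baseline in ethanol (horizontal axis) and in 1,25D (vertical axis) for the 214 tested miRNAs; red points passed the adjusted threshold in ethanol and the dashed line marks equal changes. All 30 red points have the same sign on both axes.

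Averages over both agents or both arms were added after the data were seen. Averaged over both agents, knockdown changed 44 miRNAs (20 up, 24 down, by edgeR), and 29 (13 up, 16 down) without the pair of baseline libraries apart. Of the 18 members of the myoblast list 8 fell, with miR-23a-3p, miR-31-5p and miR-503-5p beside the 5 that fell in ethanol (camera adjusted p = 0.00195; adjusted p = 0.438 with an estimated correlation; fry adjusted p = 0.00237). With the size factors of DESeq2 miR-31-5p and miR-503-5p no longer passed, and the count was 28 up and 19 down. With each of the 16 libraries left out in turn, miR-31-5p lost its call in 14 cases (all but baseline ethanol 2 and baseline 1,25D 2), with values from -0.55 to -0.41. miR-503-5p lost it in 14 (all but knockdown ethanol 3 and knockdown 1,25D 2), with values from -0.80 to -0.54. miR-155-5p lost it in 6 (baseline ethanol 1, baseline 1,25D 4, and knockdown ethanol and 1,25D 3 and 4; -0.81 to -0.53 over all 16), and miR-23a-3p in 1 (baseline ethanol 1, -0.64). Averaged over both arms, 1,25D changed 0 miRNAs by edgeR (9 with an unadjusted p under 0.05), against 1 by DESeq2 (11 unadjusted), miR-129-5p, and 0 by limma-voom (14 unadjusted). miR-129-5p had the smallest p (0.81, SE 0.20; adjusted p = 0.145). The fibrosis list was lower in that average (camera adjusted p = 0.0436), and not with an estimated correlation (adjusted p = 0.635).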

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

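The tests of a pool or sequencing batch and of muscle differentiation below, the GC offset, the 2 averaged comparisons and the alternatives without a pair of baseline libraries were chosen only after the result was seen.

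The first pattern is the rise of 13 miRNAs with VDR knockdown in ethanol, among them miR-4488, miR-3656, miR-3960 and miR-1268a. The tables argue against 3 technical explanations as the whole cause. GC content may explain a part. Across the 214 miRNAs the knockdown effect correlated with hairpin GC content (Spearman 0.27 in ethanol and 0.26 in 1,25D). Relative to the mean of each miRNA over the 16 libraries, levels rose with GC content in the knockdown libraries. The slopes ran from 0.0004 to 0.017 log2 units per percent. Levels fell with GC content in most baseline libraries. Because the mean is shared, a rise in the knockdown arm goes with a fall in the baseline arm by construction. With an offset per library for GC content (median 64% in these hairpins) the median log2 fold change was 1.37 (SE 0.32) against 1.71 (SE 0.35) before, and 13 of 13 stayed past the threshold. Without baseline ethanol library 1 it was 1.30 (SE 0.35, 7 of the 12 still tested past it). The depth of the libraries predicted -0.22 (SE 0.47), which is not told apart from no change. That error is too wide to exclude that depth explains part of the rise. A pool or sequencing batch that follows the arms cannot be told apart from the knockdown, because the lowest baseline total was 1.45 times the highest knockdown total and the labels do not say which libraries shared a pool, so loss of VDR may explain the rise but is not separated from batch.

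The second pattern is the fall of 17 miRNAs in the same comparison, among them miR-222-3p, miR-221-3p and miR-133a. With the GC offset (median GC content 47.3%) the median was -0.79 (SE 0.29) against -1.13 (SE 0.32) before, which argues against GC content as the whole cause, but 7 of 17 stayed past the threshold because the folds shrank. Without baseline ethanol library 1 the median was -1.03 (SE 0.30), and 4 of 17 stayed past it with smaller folds and 1 library fewer. Depth predicted -0.028 (SE 0.33), an error too wide to exclude that it explains part of the fall. Depth, a part due to GC content, and the pool or batch (the same ratio of 1.45) therefore stay open beside loss of VDR.

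The third pattern is a pair of baseline libraries, ethanol 1 and 1,25D 4, that lay apart from the other baseline libraries in the same miRNAs (Pearson r of their deviations 0.65 across the 214 miRNAs, which are not independent). The let-7 family was higher by medians of 1.51 and 0.70 in the pair. Their correlation with hairpin GC content was -0.38 and -0.27 (Spearman), between the bounds set for and against that explanation. More muscle differentiation in these cultures may be an explanation, since miR-206 was higher by 1.57 and 1.26 and miR-133a by 0.83 and 0.51. The smallest of these (0.51) does not decide it, and the remaining tested myomiR, miR-486-5p, went the other way (-0.98 and -0.20). The pair were also the deepest of all libraries (218019 and 232874 counts, the next 169742) and had the most miRNAs detected (530 and 502). Depth was not tested as an explanation of this pair. The design gives no group for this pair, and no biological explanation beyond differentiation was tested.

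Other divisions of the same libraries bear on whether chance can be excluded where there were calls. For knockdown in ethanol, 1 of 35 splits, the real one, gave its 30 calls and the highest of the others gave 0. For knockdown averaged over both agents, 1 of 100 splits gave its 44 calls, and the highest of the others gave 10. With 35 and 100 splits no smaller share was possible. The other splits also mixed the arms within a group, which widens the spread and lowers their counts. These values argue against chance but do not exclude it. Where the real count was 0 every split gives at least as many calls, so the splits say nothing about chance for 1,25D in baseline cells (35 of 35; highest other 14), 1,25D in knockdown cells (35 of 35; highest other 0), knockdown in 1,25D (35 of 35; highest other 0), the difference of the effects of 1,25D (100 of 100; highest other 1) and 1,25D averaged over both arms (100 of 100; highest other 6). For knockdown in 1,25D other values bear on it, since 34 miRNAs had an unadjusted p under 0.05 (10.7 by chance), 23 were fully separated (6.11 by chance), and all 30 called in ethanol had the same sign in libraries that are not shared, as did 173 of all 214. The split with 14 calls puts baseline ethanol 1 and 2 with 1,25D 3 and 4, so it places the pair of libraries apart on the same side and points to that structure of the samples.

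Single libraries lay far from the other 3 of their group in 12 of the 176 groups of values examined, and chance flags about 1 in 20 groups (8.8 here). In baseline ethanol 1, miR-1268a was lowest with 385 CPM (others 585 to 618) and miR-543 highest with 1670.1 CPM (others 715 to 801). In baseline ethanol 3, miR-4508 was highest with 152 CPM (others 77.3 to 86.5). In knockdown ethanol 1, miR-221-5p was lowest with 39.1 CPM (others 95.5 to 109.9). In knockdown ethanol 2, miR-145-5p was lowest with 0 CPM (others 39.1 to 89.4, all on few counts, and a count of 0 allows up to 66.0 CPM) and miR-23a-3p highest with 286 CPM (others 195 to 204). In knockdown ethanol 3, miR-181b-5p (2337 CPM, others 2696 to 2749) and miR-206 (2337 CPM, others 3497 to 3689) were lowest. In knockdown ethanol 4, miR-199a-5p was lowest with 239 CPM (others 547 to 613). In knockdown 1,25D 1, miR-6087 was lowest with 65.2 CPM (others 364 to 497) and miR-485-3p highest with 2723 CPM (others 1181 to 1330). In knockdown 1,25D 3, miR-1185-1-3p was highest with 213.0 CPM (others 102 to 114).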

How the results depend on the processing

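The averaged comparisons, the removal of baseline ethanol 1 and 1,25D 4 (the pair apart), the GC offset and the thinning were tests chosen only after the result was seen. Apart from leaving out libraries in turn, the named miRNAs past the threshold kept their direction in all 465 of their values, 400 of them still past it. Those not past it kept direction and side in 474 values, passed it in 26 and reversed direction in 18. The count for knockdown in ethanol (30) was between 21 and 33 with other scaling, filters and tests, 30 with the block and 27 with the GC offset. It was 9 with only the libraries compared (191 tested) and 9 without the pair apart (201 tested). As the median of draws thinned to the depth of the smallest library it was 14.5 (161 tested). Thinning lowered depth, removed the depth gap between the arms and cut the number tested, and these were not told apart. The settings with fewer libraries also changed which ones were used, and leaving out 1 library gave 12 to 27 calls. The effect of the number of libraries was therefore not isolated. The count for knockdown in 1,25D (0) was 3 with the size factors of DESeq2, 6 with totals alone, 2 without a filter, 7 with the block, 9 with the Wald test, 1 with only the libraries compared and 2 with the GC offset, where 10 adjusted p-values lay between 0.05 and 0.06. The count for 1,25D averaged over both arms (0) was 1 with totals alone, 1 without a filter and 1 with the Wald test, and for 1,25D in baseline cells (0) it was 1 without a filter. Averaged knockdown (44) was 29 without the pair apart. One list passed in each of 1,25D in baseline cells, knockdown in ethanol and knockdown in 1,25D, and 0 with an estimated correlation. Without the pair apart it was 0 in the first 2 of these. The calls of knockdown in both agents shared 0 miRNAs, and 6 with the block (0.981 from independent lists). Whether the numbers in the titles pair the libraries is unknown, since the labels do not say, same-number pairs correlated between -0.34 and 0.46 (median 0.071, others -0.061), 10 of 24 were over 0.1, and 5 of 16 libraries correlated best with their own number. Directions that reversed were these. miR-27a-3p with knockdown in ethanol (-0.00) was 0.083 with the size factors of DESeq2, 0.080 with the Wald test, 0.029 with limma-voom, 0.098 with only the libraries compared and 0.22 without the pair apart. In the averaged effect of 1,25D it was 0.00036 with totals alone, 0.0082 with the filter of 10 CPM and 0.041 without the pair apart. miR-486-5p was 0.0065 and 0.0069 with size factors and Wald test for knockdown in 1,25D, -0.019 with the 10 CPM filter in the difference of effects and -0.087 with the block for 1,25D in baseline cells. Without the pair apart, miR-143-3p with 1,25D in baseline cells was 0.41, and miR-206 with knockdown was 0.17 in ethanol, 0.29 in 1,25D and 0.23 averaged, where the GC offset gave 0.11 in 1,25D and 0.011 averaged. With each library left out in turn, knockdown gave 12 to 27 calls in ethanol (12 without baseline ethanol 1, 13 without knockdown ethanol 4, 15 without knockdown ethanol 2 or 3, 18 and 19 without baseline ethanol 2 and 4) and 0 to 7 in 1,25D (7 without knockdown 1,25D 1, 2 without 3). For 1,25D in baseline cells, miR-143-3p ranged from -2.26 to 0.29 (the latter without baseline ethanol 1), miR-206 from -0.22 to 0.60, miR-486-5p from -0.18 to 0.35 and miR-27a-3p from -0.45 to 0.073. In knockdown cells miR-133a ranged from -1.10 to 0.29, miR-486-5p from -0.050 to 0.44 and miR-27a-3p from -0.15 to 0.62. With knockdown in ethanol miR-206 ranged from -0.61 to 0.080, miR-486-5p from -0.38 to 0.13 and miR-27a-3p from -0.29 to 0.39; in 1,25D miR-206 ranged from -0.44 to 0.29 and miR-486-5p from -0.29 to 0.21. In the difference of effects miR-133a ranged from -0.18 to 1.20, miR-206 from -0.073 to 0.68 and miR-486-5p from -0.22 to 0.37. Averaged, 1,25D gave -0.00036 to 0.30 for miR-486-5p and -0.22 to 0.21 for miR-27a-3p, and knockdown gave -0.45 to 0.044 for miR-206 and -0.22 to 0.056 for miR-486-5p. The cause of these differences was not tested. The alternatives foreseen for normalized values (pseudocount and filter) did not apply to counts.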

Other observations

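The tests of miR-129-5p and of late-numbered miRNAs below, and the bootstrap interval of the hairpin arms, were chosen only after the result was seen. With VDR knockdown in ethanol, miRNAs numbered 1000 or higher, most of which were described late, took a larger share of counts. The 50 tested ones took 9.31% ± 1.62 of counts in baseline cells and 15.5% ± 3.19 in knockdown cells (SD, n = 4), with 10.2% ± 0.908 and 12.4% ± 3.06 in 1,25D. Most of that growth in ethanol came from miR-1260a and miR-1260b, which may be the same reads counted under both names and went from 5.75% ± 1.14 to 10.7% ± 2.80. The other 48 went from 3.56% ± 0.518 to 4.80% ± 0.415. The median log2 fold change of all 50 in ethanol was 0.54, against -0.22 for the tested miRNAs with lower numbers. The 50 made up 10 of the 13 that rose and 40 of the other 201 (two-sided Fisher's exact p = 3.63e-05), but 3 of the 17 that fell (exact p = 0.768). With 1 name kept of each of the pairs miR-1260a/b and miR-1268a/b it was 8 of 11 against 40 of 201 (exact p = 0.000395). The miRNAs are not independent and the grouping was noticed among these same risers, so these p-values are only descriptive. Hairpin GC content of the 10 late-numbered risers ran from 43.8% (miR-1246) to 87.9% (miR-3960). Its part in the rise was not separated from the numbering. The origin of the reads of these names was not tested.

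The arms of a hairpin come from the same transcript, so a change in its transcription may move both. Over 28 hairpins with both arms tested, the averaged knockdown effects on the 5p and 3p arms had a Pearson r of -0.13 across hairpins (Spearman -0.18; 100000 permutations, p = 0.493), and 10 had the same sign. The bound set before the test asked only for a p of 0.05 or more, which excludes nothing here, because the 95% bootstrap interval of r ran from -0.59 to 0.31. Changes of whole hairpins therefore stay open.

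miR-129-5p may be a miRNA raised by 1,25D whether or not VDR is depleted. It lay at 156 to 303 CPM with ethanol and 305 to 516.3 with 1,25D in baseline cells, and at 220 to 396 and 489 to 625 CPM in knockdown cells. It was the 1 miRNA whose groups did not overlap in the same direction in both arms, where 0.0873 are expected by chance (exact permutation p within arms 0.000408 for such a miRNA; 4 and 5 miRNAs separated in one arm, 6.11 expected). In baseline cells that separation rests on 302.7 CPM in ethanol 4 against 304.6 CPM in 1,25D 4, a gap smaller than a single count in either library (6.44 and 4.17 CPM). Its adjusted p in the averaged comparison was 0.145, so chance among the 214 tested was not excluded. Its counts were between 10 and 85 per library.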
